A study of Mus musculus with 12 samples.

How the data were processed

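RNA from RAW 264.7 cells was extracted with RNeasy columns and labelled with biotin for an Affymetrix mouse array, per the labels' protocols. The 12 arrays were grouped by treatment as the labels give it, with 3 arrays each for LPS alone, TsSP with LPS, inulin with LPS, and inulin and TsSP with LPS. Nothing in the labels says that the 3 arrays of a group came from separate cultures.

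The deposited table gives 1 value per probe set and array on a log2 scale. The base of the logarithm is inferred from the values, which run from 1.32 to 18.9, and the background correction, normalization and software by which the authors made them are not given in the sources used here. The scale enters every fold below, and any compression of bright or dim signals by that processing would be carried into them. The values were used as deposited, with no further normalization, and the array medians are given in the results.

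The table holds 28846 probe sets. Of these, 19572 have 1 gene symbol in the array's annotation and 0 have several, and all 19572 were matched by gene number to the RefSeq annotation of assembly GRCm38.p6, which was used for names only. A further 2634 transcript clusters have no name here, and the rest are intron, exon, background, spike and hybridization controls. For 55 genes with several probe sets, the probe set with the highest mean signal stood for the gene, which left 19505 genes. A gene counted as above background in a group when it lay above the brightest of 23 background probes on each of the group's arrays, and 9022 genes did so in at least 1 group. Where a called gene was below background on some or all arrays of the dimmer group of a comparison, its change is given as at least N-fold: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the background level and the gene's own signal. Where both groups were below background, no fold is given.

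Each comparison was a contrast in a single limma model with a mean for each of the 4 groups (lmFit and eBayes, limma 3.58.1 in R 4.3.3), which pools the spread over all 12 arrays (8 residual degrees of freedom, 3.35 prior degrees of freedom). The 6 contrasts were TsSP against LPS alone, inulin against LPS alone, both against LPS alone, inulin added to TsSP, TsSP added to inulin, and the interaction. An F test over the 4 groups was run as well. P-values are two-sided and adjusted by Benjamini and Hochberg over the 19505 genes of each contrast, with a threshold of 0.05. Folds are 2 to the power of the difference of mean log2 signals, and SE is the standard error of that difference from limma. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

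The gene lists hold inflammatory cytokines and chemokines, the NF-kB pathway, interferon-stimulated genes, alternative activation, anti-inflammatory regulators, cholesterol biosynthesis, LXR targets, NRF2 targets, the unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, the cell cycle, antigen presentation, pattern recognition, the lysosome, immediate early genes, p53 targets, prostaglandin enzymes, matrix remodelling, ribosomal proteins, and markers of macrophages, osteoclasts, dendritic cells, neutrophils and mast cells, lymphocytes, and fibroblasts and epithelia. These 26 lists name 802 members, of which 736 were measured, and 65 distinct genes, Il12b among them, are not analysed here. An older name was matched through its synonym only where no gene bears it now. That condition was added after list results had been seen, because synonyms had put other genes in the place of 4 members, and it ended 1 list call, that of the LXR list for inulin added to TsSP. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted by Benjamini and Hochberg over all 156 tests of 26 lists in 6 contrasts, again with a correlation estimated from the arrays, and with fry, which tests whether members move on balance one way without comparing them with other genes. Over the 6 contrasts camera made 27 calls of 156, 21 were made with an estimated correlation and 52 with fry. In contrasts other than TsSP against LPS alone, median, mean and test differed in sign only in lists that camera did not call. Members were counted at the all-gene threshold and with p-values adjusted over the list alone.

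The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls past the threshold in each comparison with LPS alone, with all 3 arrays of one group on one side of the 3 of the other, leaving out predicted genes, small RNA genes and chemosensory receptors. It took 5 and 5 for the additions and the interaction, and in each case 12 genes of macrophage activation (Tnf, Il6, Il1b, Il10, Il12b, Nos2, Ptgs2, Ccl2, Arg1, Ifnb1, Hmox1 and Cd14). It also took up to 4 members of each list by smallest p, more where a count of 5 or fewer is stated, and the 10 smallest p-values where fewer than 10 genes passed. Genes named outside it, such as list members that did not pass, were chosen after their values were seen. Near-identical families, such as Sprr2d, Sprr2e and Sprr2f, Bcl2a1a, Bcl2a1b and Bcl2a1d, Tgtp2 and Ifit3, are uncertain because probes may not tell their members apart.

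The model was tested on simulated data in which 200 of 19505 genes were changed. For the inulin contrast it recovered 88.0% of 2-fold, 98.0% of 4-fold and 34.0% of 1.5-fold changes, and for the TsSP contrast 78.0%, 98.0% and 40.0%, with 11 and 13 false calls. The list test was run on data in which the cell cycle list was shifted, and it called that list and 0 of the 25 others. The simulated noise was independent between genes, so this run says nothing about false list calls that arise from correlated genes. Alternatives were median-centring, quantile normalization, array weights, a mean-variance trend, a block for the replicate number, a filter on dim genes, all probe sets tested, a stricter threshold, a fold filter, a fit of the 6 arrays of a comparison alone, and leaving out each array in turn. A filter to genes above background, the average of both inulin contrasts, counts of list members that passed without LPS replicate 1, and an overlap between comparisons with no shared arrays were chosen after seeing the data. The overlap of comparisons that share the LPS arrays was set against simulations of unchanged groups against those arrays.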

Results

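Gene expression was measured in RAW 264.7 cells, a macrophage-like line of mouse origin, with 1 Affymetrix array per sample. The 12 arrays formed 4 groups of 3. All groups received lipopolysaccharide (LPS), a component of bacterial outer membranes that activates macrophages, at 500 ng/mL. One group received LPS alone, one LPS with inulin (a plant fructan used as a dietary fibre) at 500 µg/mL, one LPS with a preparation labelled TsSP at 50 µg/mL, and one LPS with both. The design text of the series speaks of helminth products, and the abbreviation TsSP is used here as it stands in the labels. The cells were kept for 6 hours at 37°C in 5% CO2. No array without LPS was used, so every change below is a change within LPS-stimulated cells.

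The median log2 signal over all probe sets lay between 5.16 and 5.3 on the 12 arrays, and between 8771 and 9059 of 19505 genes lay above the brightest background probe of their array. Across genes, arrays of one group correlated at r = 0.993 to 0.995, and arrays with TsSP correlated at r = 0.985 to 0.987 with arrays without it. The first principal component held 48.2% of the variance and parted the 6 arrays with TsSP from the 6 without. The second held 7.40% and set LPS replicate 1 apart from the other arrays. This array had the lowest median signal, 5.16, and the lowest background median, 4.99 against 5.2 to 5.43 elsewhere. The median of the exon control probe sets lay at 11.22 to 11.36 on the 6 arrays with TsSP and at 11.00 to 11.21 on the 6 without. With 3 arrays per group, their number limits the precision. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

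The first comparison asked which genes differ when TsSP is present during LPS stimulation. With TsSP, the inflammatory cytokine gene Tnf was 6.09-fold lower than with LPS alone, at a log2 signal of 14.69 ± 0.14 against 17.30 ± 0.060 (mean ± SD, n = 3 in each group, standard error of the log2 difference 0.12, adjusted p = 9.01e-08). Il6, another inflammatory cytokine gene, fell 4.30-fold (log2 SE 0.11), the monocyte-attracting chemokine gene Ccl2 fell 3.22-fold (log2 SE 0.10), and the inducible nitric oxide synthase gene Nos2 fell 2.38-fold (log2 SE 0.17). Smaller falls were measured for Il1b, at 1.91-fold (log2 SE 0.13), and for Ptgs2, the inducible cyclooxygenase gene, at 1.77-fold (log2 SE 0.10). Il10, which encodes an anti-inflammatory cytokine, moved the other way and rose 2.70-fold, from 10.20 ± 0.14 to 11.63 ± 0.075 (mean log2 signal ± SD, n = 3, adjusted p = 1.16e-05). Hmox1, the haem oxygenase gene, rose 4.42-fold (log2 SE 0.10). Cd14, which encodes an LPS co-receptor, differed by 0.13 on the log2 scale (SE 0.10, adjusted p = 0.479) and did not pass the test. In each of these genes all 3 TsSP arrays lay on one side of the 3 LPS arrays, and in each except Cd14 the adjusted p passed 0.05. Arg1 and Ifnb1 lay below the background probes in both groups and have no fold, although Ifnb1, the interferon beta gene, passed the test as lower (adjusted p = 0.0105), and Il12b was not analysed here.

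**Figure D1:**
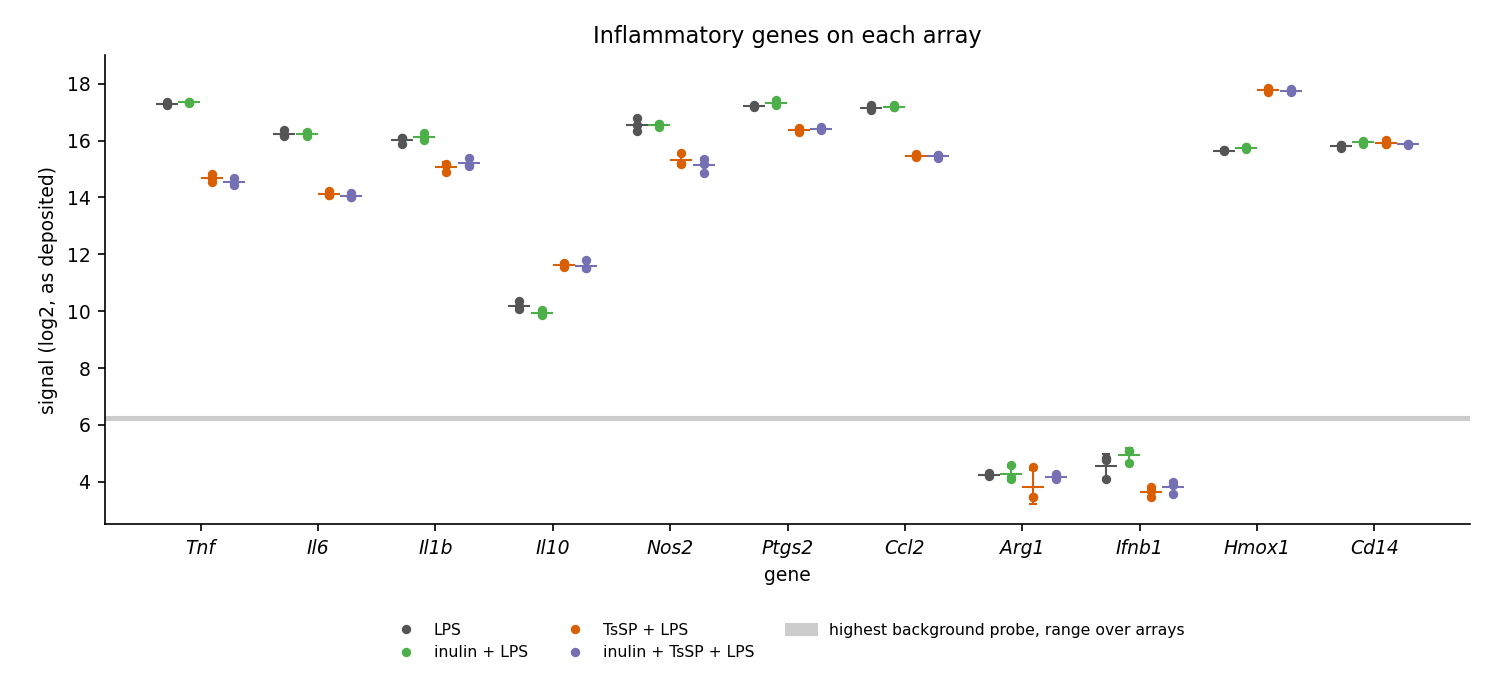
Log2 signal (vertical axis, as deposited) of 11 inflammatory genes on each of the 12 arrays, one dot per array, with horizontal ticks at the group means, error bars of 1 SD and a grey band for the range of the brightest background probe over the arrays. Both groups with TsSP lie below both groups without it for Tnf, Il6, Il1b, Nos2, Ptgs2 and Ccl2 and above them for Il10 and Hmox1, while Arg1 and Ifnb1 lie under the band in all 4 groups.

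The 10 largest falls were led by Il27, which encodes a subunit of the cytokine interleukin-27, at 39.6-fold (transcript cluster TC0700004287.mm.2, log2 SE 0.14, adjusted p = 5.35e-09). The interferon-induced chemokine gene Cxcl9 fell 23.3-fold, the leukocyte receptor gene Slamf7 21.4-fold, Ptchd1 21.3-fold, the guanine nucleotide exchange factor gene Rasgef1b 19.6-fold and the activation marker Cd69 16.01-fold, with log2 SE of 0.17, 0.15, 0.19, 0.14 and 0.11 in that order. Kynu, which encodes an enzyme of tryptophan breakdown, was above background on 1 of 3 TsSP arrays and at least 12.0-fold lower, and the interferon-induced GTPase gene Tgtp2 fell 13.9-fold, although probes for Tgtp2 may also read near-identical family members. Ch25h, which encodes an oxysterol-making hydroxylase, and Csf2, the gene of a granulocyte and macrophage growth factor, dropped below background with TsSP and were at least 9.39-fold and at least 4.85-fold lower. The 10 largest rises were led by Il19, which encodes a cytokine of the Il10 family, at 33.7-fold (transcript cluster TC0100003050.mm.2, log2 SE 0.18, adjusted p = 1.91e-08). Bnip3, which encodes a mitochondrial protein of mitophagy, rose 18.4-fold and Tifab 15.7-fold, with log2 SE of 0.14 and 0.23. The pyruvate dehydrogenase kinase gene Pdk1 and Rab3il1, above background on 2 and 1 of the 3 LPS arrays, were at least 12.9-fold and 12.8-fold higher. S100a8, which encodes a calcium-binding protein of myeloid cells, the membrane protein gene Tm4sf1 and the glycogen-targeting phosphatase subunit gene Ppp1r3b were below background with LPS alone and at least 5.82-fold, 6.38-fold and 3.14-fold higher with TsSP. Sprr2e and Sprr2d, members of a family of near-identical small proline-rich protein genes, rose 23.4-fold and 19.7-fold, and which member was measured is uncertain.

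In all, limma called 3525 of 19505 genes at an adjusted p under 0.05, of which 2144 were higher and 1381 lower with TsSP. Of 2860 called genes that lay above background on all arrays of both groups, 819 differed more than 2-fold and 122 more than 4-fold, 55 higher and 67 lower. Genes that lay above background in none of the 4 groups made up 375 of the calls. The share of higher calls was 60.8%. It was 50.9% after quantile normalization, with 1693 higher and 1631 lower, and 55.7% without LPS replicate 1, with 3090 genes called.

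Gene lists chosen for macrophages before the data were examined were tested with limma's camera, which compares a list with all other genes. Of the inflammatory cytokines and chemokines, 28 of 33 measured members fell and 0 rose (29 fell when adjusted over the list alone; median log2 change -1.39, adjusted p = 7.57e-32). The smallest p-values belonged to Il27, Il1a at 7.33-fold lower, Cxcl9 and the macrophage growth factor gene Csf1 at 6.16-fold lower. The members that did not pass were Ccl9, Cxcl1, Cxcl3, Il12a and Tnfsf9, with log2 changes of -0.081, -0.40, -0.40, -0.61 and -0.10. Of the interferon-stimulated genes, 35 of 40 fell and 0 rose (36 fell when adjusted over the list alone; median -0.72, adjusted p = 3.45e-28), among them the GTPase gene Iigp1 at 12.5-fold, the antiviral genes Ifit1 at 3.51-fold and Ifit3 at 3.44-fold, and the transcription factor gene Irf1 at 4.11-fold. Eif2ak2, Irf7, Irf9, Isg20 and Oasl2 did not pass, with log2 changes from -0.29 to -0.11. Of the genes of the NF-kB pathway and its feedback, 18 of 30 fell and 1 rose (20 and 1 when adjusted over the list alone; median -0.60, adjusted p = 2.45e-13). The adhesion molecule gene Icam1 fell 5.02-fold and the survival genes Bcl2a1a, Bcl2a1b and Bcl2a1d fell 9.41-fold, 10.6-fold and 8.75-fold, though these near-identical copies cannot be taken as separate measurements. The gene that rose was Bcl3, which encodes an atypical member of the IkB family, at 1.76-fold. Of the antigen presentation and costimulation genes, 13 of 27 fell and 1, the costimulatory Cd80, rose 2.17-fold (14 and 1 when adjusted over the list alone; median -0.40, adjusted p = 5.91e-06). Icosl and Cd274, which encode ligands of T-cell receptors of costimulation and inhibition, fell 5.69-fold and 2.66-fold, the costimulatory receptor gene Cd40 fell 2.60-fold, and the immunoproteasome gene Psmb10 fell 1.93-fold.

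Other lists rose with TsSP, against a median log2 change of 0.17 over the exon control probe sets. Of the cholesterol biosynthesis genes, 19 of 21 rose and 0 fell (20 rose when adjusted over the list alone; median log2 change 1.09, adjusted p = 1.22e-14). The sterol pathway enzyme genes Mvd, Sqle and Lss rose 3.87-fold, 2.68-fold and 2.61-fold, and Insig1, which encodes a sterol-responsive regulator, rose 2.74-fold, while Srebf2 and Ggps1 did not pass, at 0.32 and -0.30 on the log2 scale. Of the glycolysis and hypoxia genes, 22 of 32 rose and 2 fell (26 and 2 when adjusted over the list alone; median 0.91, adjusted p = 6.75e-15). Besides Bnip3 and Pdk1, the oxygen-sensing prolyl hydroxylase gene Egln1 rose 6.88-fold, the phosphofructokinase gene Pfkl 4.84-fold and the Myc antagonist gene Mxi1 5.82-fold. The members that fell were Pfkp, another phosphofructokinase gene, at 1.28-fold and Acod1, the gene of the itaconate-making enzyme, at 1.39-fold. With 1 array left out in turn, Pfkp lost its call in 8 of 12 fits, with an adjusted p of up to 0.11 without TsSP replicate 3. Of the NRF2 oxidative stress genes, 20 of 27 rose and 1 fell (21 and 1 when adjusted over the list alone; median 0.68, adjusted p = 8.36e-13). Osgin1 rose 4.91-fold, the haem transporter gene Slc48a1 3.76-fold and the glutathione synthesis gene Gclm 2.38-fold, and the member that fell was Keap1, which encodes the repressor of NRF2, at 1.49-fold. These 7 lists kept an adjusted p under 0.05 with a correlation estimated from the arrays, the largest being 0.00831 for the NF-kB list.

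**Figure D2:**
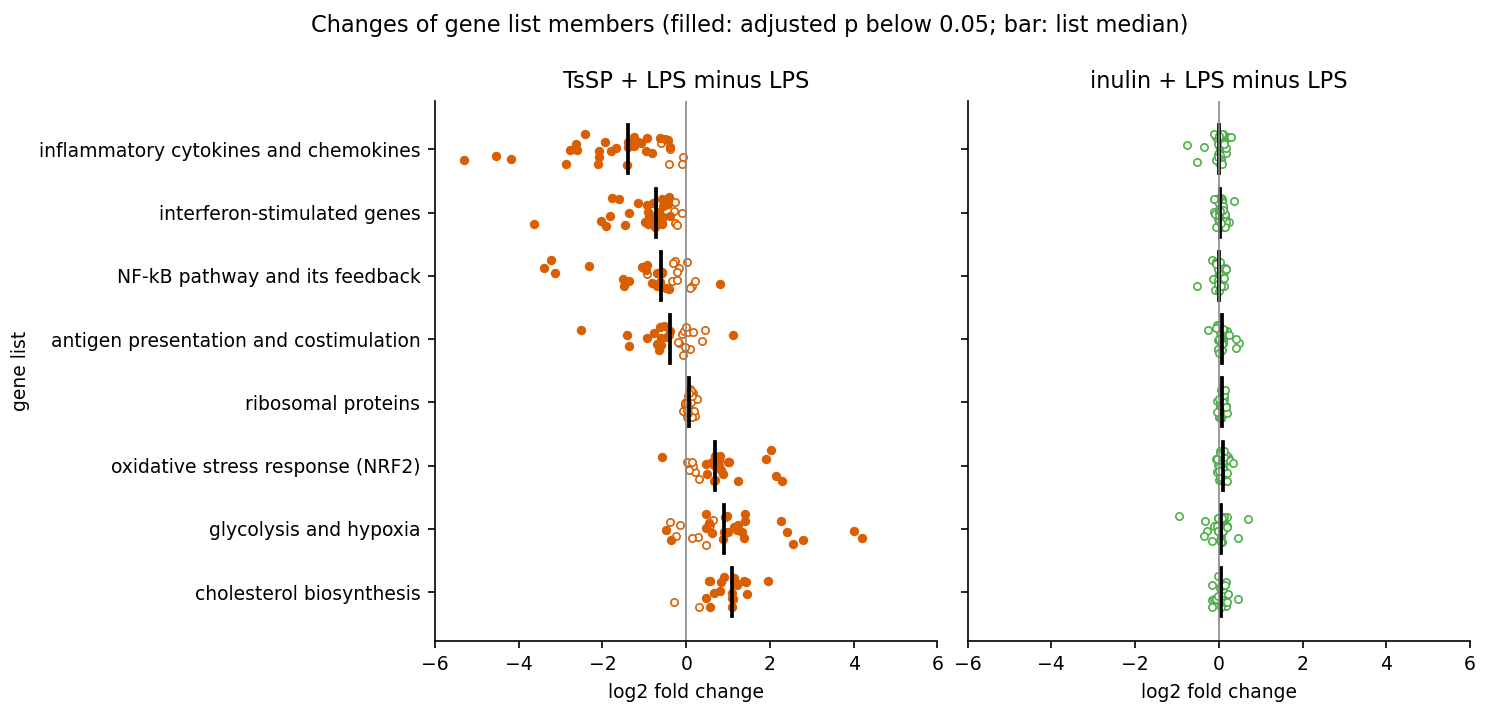
Log2 fold change (horizontal axis) of every measured member of 8 gene lists (vertical axis) for TsSP with LPS against LPS alone on the left and for inulin with LPS against LPS alone on the right, with filled dots for members at an adjusted p under 0.05 and a black bar at each list median. On the left the cytokine list has its median at -1.39 and the cholesterol list at 1.09, and on the right no dot is filled.

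The other 3 lists that camera called lost the call when the correlation between genes was estimated. Of the oxidative phosphorylation and TCA cycle genes, 6 of 37 rose, led by the respiratory chain genes Ndufa4 at 1.52-fold and Cox7a2 at 1.47-fold, and 0 fell (5 rose when adjusted over the list alone; adjusted p = 0.00639, and adjusted p = 0.548 with an estimated correlation). The median log2 change of this list was 0.19, near the 0.17 of the exon control probe sets. Of the cell cycle genes, 11 of 37 rose, such as the ribonucleotide reductase gene Rrm2 at 2.83-fold, and 3 fell, namely Cdt1, Mcm6 and Cenpe at 1.63-fold, 1.66-fold and 1.5-fold (12 and 4 when adjusted over the list alone; adjusted p = 0.0237, and adjusted p = 0.742 with an estimated correlation). The cell cycle call was also lost after quantile normalization and without LPS replicate 3, at adjusted p = 0.106 and 0.0569. Of the p53 targets and apoptosis genes, 9 of 28 fell, led by the kinase gene Plk2 at 7.33-fold and Mdm2, which encodes the ubiquitin ligase of p53, at 2.76-fold, and 5 rose, namely Ccng1, Trp53inp1, Sesn1, Zmat3 and Ei24 (12 and 6 when adjusted over the list alone; adjusted p = 0.0187, and adjusted p = 0.286 with an estimated correlation). Leaving out 1 array in turn ended the calls of Ccng1, Sesn1 and Zmat3 in 4, 4 and 1 of 12 fits, with adjusted p of up to 0.0606 and 0.102 without LPS replicate 3 and 0.0512 without TsSP replicate 2. Sesn1 also lost its call after quantile normalization, at adjusted p = 0.0875.

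In lists that camera did not call, members often moved both ways. Of the anti-inflammatory regulators, 10 of 28 rose and 10 fell (11 and 11 when adjusted over the list alone; adjusted p = 0.981), with Hmox1 and Il10 among those that rose, Tnfaip3, an NF-kB inhibitor gene, 2.79-fold lower, and the cytokine signalling inhibitor gene Cish at least 3.06-fold lower. The median of this list was above 0 and its mean and test below 0. Of the LXR targets and lipid handling genes, 7 of 23 rose, with the cholesterol exporter gene Abca1 8.00-fold higher, and 6 fell, with Mylip and the exporter gene Abcg1 2.95-fold and 2.60-fold lower (8 and 7 when adjusted over the list alone; adjusted p = 0.742). Its median was above 0, and below 0 after centring each array, while its mean and test were below 0. Of the unfolded protein and integrated stress response genes, 9 of 32 rose, with the endoplasmic reticulum chaperone gene Creld2 2.53-fold higher, and 12 fell, with Chac1 and Sesn2 4.8-fold and 4.28-fold lower (10 and 14 when adjusted over the list alone; adjusted p = 0.542). Of the immediate early and MAPK feedback genes, 10 of 41 rose, with Fos 4.00-fold higher, and 13 fell, with the stress transcription factor gene Atf3 and Gadd45b 2.38-fold and 2.67-fold lower (11 and 15 when adjusted over the list alone; adjusted p = 0.542). Of the pattern recognition and phagocytic receptors, 11 of 41 rose, with the lectin receptor genes Clec4a2 and Clec4n 5.75-fold and 2.75-fold higher, and 11 fell, with the inflammasome sensor gene Nlrp3 and the receptor gene Tlr1 3.30-fold and 2.63-fold lower (12 and 11 when adjusted over the list alone; adjusted p = 0.960). The median of the immediate early list was above 0, and below 0 under the other scalings, with mean and test below 0, and the median and mean of the pattern recognition list were above 0 with the test below 0.

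Of the matrix remodelling and adhesion genes, 10 of 36 rose, with the metalloproteinase gene Adam8 2.63-fold higher, and 5 fell, namely Icam1, Itga4, Itga5, Plau and Adamts4 (10 and 7 when adjusted over the list alone; adjusted p = 0.922), with median and test above 0 and the mean below 0. Of the prostaglandin and leukotriene genes, 5 of 23 rose, namely Pla2g7, Abcc4, Alox5ap, Hpgds and Ptger2 at 3.19-fold, 3.43-fold, 2.42-fold, 1.75-fold and 1.66-fold, and 1, Ptgs2, fell (5 and 1 when adjusted over the list alone; adjusted p = 0.244). Of the alternative activation genes, 2 of 29 rose, namely the interleukin-4 receptor gene Il4ra at 2.68-fold and Stat6, which encodes its signal transducer, at 1.83-fold, and 5 fell, namely the chemokine genes Ccl22 at 3.68-fold and Ccl17 at least 1.88-fold, with Klf4, Socs2 and Myc (2 and 5 when adjusted over the list alone; adjusted p = 0.629). Of the lysosome genes, 4 of 35 rose, namely Ctsl, Atp6v0d1, Gusb and Atp6v1a, each under 1.5-fold, and 2 fell, namely the transcription factor gene Mitf at 3.09-fold and Atp6v1b2 at 1.41-fold (4 and 2 when adjusted over the list alone; adjusted p = 0.844). Leaving out 1 array in turn ended the calls of Myc, Atp6v1a and Ptger2 in 11, 5 and 1 of 12 fits, with adjusted p of up to 0.121 without TsSP replicate 2, 0.0858 without TsSP replicate 3 and 0.0570 without TsSP replicate 2. None of the 27 measured ribosomal protein genes passed the test, alone or adjusted over the list alone (median log2 change 0.075, adjusted p = 0.542). The log2 changes of the ribosomal protein genes with the smallest p-values, Rps15, Rps4x, Rpl11 and Rpl7, were 0.27, 0.19, 0.20 and 0.19. These 4 passed with a mean-variance trend in limma, at adjusted p = 0.00384, 0.0463, 0.0277 and 0.0310, and Rps15 also over genes above background alone, at adjusted p = 0.0345.

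Of the macrophage lineage markers, 7 of 25 rose, with the transcription factor gene Irf8 3.69-fold and the integrin gene Itgam 1.67-fold higher, and 3 fell, namely Adgre1, which encodes the F4/80 antigen, at 2.08-fold, Runx1 at 1.54-fold and Maf at 1.36-fold (7 and 4 when adjusted over the list alone; adjusted p = 0.386). The macrophage markers that rose and fell numbered 4 and 4 after quantile normalization, 5 and 4 after centring each array, and 4 and 3 without LPS replicate 1. Of the osteoclast markers, 2 of 16 rose, namely the fusion protein gene Dcstamp at least 1.77-fold and Ostm1 at 1.63-fold, and 1, the chloride transporter gene Clcn7, fell 2.59-fold (2 and 1 when adjusted over the list alone; adjusted p = 0.693). Markers of neutrophils, mast cells, lymphocytes, dendritic cells, fibroblasts and epithelia lay mostly below background. Of 18 neutrophil and mast cell markers, 3 were above background in a group, and 2 rose, S100a8 and the growth factor receptor gene Csf3r at 1.48-fold (2 when adjusted over the list alone; adjusted p = 0.816). Csf3r did not pass without LPS replicate 1, at adjusted p = 0.0637, and lost its call in 3 of the 12 fits with 1 array left out, with an adjusted p of up to 0.0886 without TsSP replicate 3. Of 16 lymphocyte markers and 15 dendritic cell markers, 1 in each list was above background, and the calls in them were 0 and 1, the latter for Fscn1, which lay below background in both groups (none when adjusted over the list alone; adjusted p = 0.542 for both lists). The dendritic cell marker Cd83, also in the NF-kB list, did not pass with its brightest probe set. With the mean of its probe sets it passed in limma as lower, at -1.04 on the log2 scale and adjusted p = 0.00184. Cd83 also passed with a mean-variance trend and without LPS replicate 2, at adjusted p = 0.0385 and 0.0311. With 1 array left out it passed in 1 of 12 fits, with an adjusted p of up to 0.269 without TsSP replicate 1. The lymphocyte marker Cd5, at -0.70 on the log2 scale (adjusted p = 0.0554), passed as lower after quantile normalization, after centring and without LPS replicate 1, at adjusted p = 0.0113, 0.0320 and 0.0329. It also passed with a mean-variance trend, with array weights, with the dimmest genes left out and over genes above background alone, at adjusted p = 0.0365, 0.0370, 0.0379 and 0.0203. With 1 array left out, Cd5 passed in 3 of 12 fits, with an adjusted p of up to 0.175 without LPS replicate 2. The mast cell marker Mcpt4 passed as lower after centring, with the replicate block and without LPS replicate 1, at adjusted p = 0.0473, 0.0366 and 0.0365. The fibroblast marker Dcn passed as lower after quantile normalization and over genes above background, at adjusted p = 0.0223 and 0.0462. Of 19 fibroblast and epithelial markers, 3 were above background and 1, Col3a1, was called lower while below background in both groups (none when adjusted over the list alone; adjusted p = 0.542). Leaving out 1 array in turn ended the calls of Maf, Runx1, Fscn1 and Col3a1 in 10, 1, 9 and 4 of 12 fits, with adjusted p of up to 0.147 and 0.0502 without TsSP replicate 3, 0.157 without LPS replicate 2 and 0.117 without LPS replicate 3. With fry, the macrophage, neutrophil and mast cell, prostaglandin, unfolded protein response and LXR lists passed as well, at adjusted p = 0.00191, 0.0103, 8.88e-04, 0.00725 and 0.0328. Their median log2 changes were 0.16, 0.055, 0.19, -0.21 and 0.025 in that order, against 0.17 over the exon control probe sets. Since fry does not compare a list with other genes, a general shift of the arrays can enter these calls.

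The next comparison asked what inulin changes in LPS-stimulated cells. No gene passed the test. With inulin, Tnf differed from LPS alone by 0.044 on the log2 scale (SE 0.12, n = 3 per group, adjusted p = 0.985), Il6 by -0.00082 (SE 0.11), Il1b by 0.11 (SE 0.13), Nos2 by -0.021 (SE 0.17) and Il10 by -0.27 (SE 0.13). limma called 0 of 19505 genes, with 1143 at an unadjusted p under 0.05 where 975 would be expected with no effect, and a smallest adjusted p of 0.332. The smallest p-values belonged to Ube2t, which encodes a ubiquitin-conjugating enzyme of DNA repair, at a log2 difference of 1.24 (SE 0.18), and among other genes above background Sult1c1, a sulfotransferase gene, at 0.73 (SE 0.12) and Efcab7 at 0.81 (SE 0.14), each with an adjusted p of 0.332. Among the 9022 genes above background, the 95% interval of the inulin difference lay within 2-fold for 96.7% and within 1.5-fold for 74.7%.

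No gene list passed camera for inulin. The smallest adjusted p belonged to the NRF2 oxidative stress list, with a median log2 difference of 0.10, 0 of 27 members past the threshold and 0 when adjusted over the list alone (adjusted p = 0.0625, and adjusted p = 0.635 with an estimated correlation). It passed without LPS replicate 1, at adjusted p = 0.0473, and with fry, which asks whether the members of a list move on balance one way, at adjusted p = 0.0438. Without inulin replicate 3 the oxidative phosphorylation list passed, at adjusted p = 0.0399. With fry the antigen presentation list passed as well, at adjusted p = 0.0366 and a median of 0.066. The inflammatory cytokine and interferon-stimulated lists had medians of 0.014 and 0.033 (adjusted p = 0.932 and 0.624).

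The third comparison set inulin and TsSP together against LPS alone. Tnf was 6.72-fold lower (log2 SE 0.12, n = 3 per group, adjusted p = 6.15e-08), Il6 4.55-fold lower (log2 SE 0.11), Ccl2 3.25-fold lower (log2 SE 0.10), Il10 2.65-fold higher (log2 SE 0.13) and Hmox1 4.29-fold higher (log2 SE 0.10). The largest falls were those of Il27 at 35.9-fold, Slamf7 at 26.2-fold and Cxcl9 at 23.3-fold, with Ch25h, Csf2 and the chemokine gene Ccl20 below background and at least 8.92-fold, 4.61-fold and 5.37-fold lower. The largest rises were those of Il19 at 33.9-fold, Bnip3 at 20.2-fold and Pdk1 at least 14.1-fold, with the uncertain Sprr2 family members and with S100a8 and the adaptor gene Bcar1 at least 5.86-fold and 2.25-fold higher. limma called 3433 genes, 2010 higher and 1423 lower. The share of higher calls was 58.5%, 48.9% after quantile normalization and 53.1% without LPS replicate 1, with 3010 genes called.

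In this comparison 28 of 33 cytokine and chemokine genes fell (median log2 change -1.43, adjusted p = 4.55e-32), as did 36 of 40 interferon-stimulated genes (median -0.73, adjusted p = 2.09e-28), 18 of 30 NF-kB genes (median -0.59, adjusted p = 4.58e-14) and 13 of 27 antigen presentation genes (median -0.31, adjusted p = 7.65e-06). When adjusted over the list alone, 29, 37, 22 and 15 members fell. Bcl3 and Cd80 were the members of these lists that rose. Of the cholesterol biosynthesis genes 19 of 21 rose (median 0.97, adjusted p = 1.38e-14), of the glycolysis and hypoxia genes 24 of 32 (median 0.89, adjusted p = 3.22e-15) and of the NRF2 genes 20 of 27 (median 0.69, adjusted p = 1.33e-12), and 20, 24 and 21 when adjusted over the list alone. Pfkp and Acod1 in the glycolysis list and Keap1 in the NRF2 list fell. The p53 list was called lower, with 12 of 28 members falling (adjusted p = 0.00458), and adjusted p = 0.176 with an estimated correlation. The oxidative phosphorylation list was called higher, with 7 of 37 members rising (adjusted p = 0.0159), and adjusted p = 0.635 with an estimated correlation. That call was also lost without LPS replicate 3 and without replicate 1 of the combined group, at adjusted p = 0.0514 and 0.0527. The cell cycle list did not pass with camera (adjusted p = 0.0695). It passed without replicate 2 of the combined group, at adjusted p = 0.0475, and with fry, at adjusted p = 0.00608. In this comparison fry called 18 of the 26 lists.

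Of the genes called for TsSP and for the combination, 1705 were higher in both and 1146 lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 221 and 101 genes. Both comparisons use the same 3 LPS arrays, and simulated unchanged groups against those arrays shared 0 calls. That count decides nothing, since unchanged groups have few if any calls to share. The log2 changes correlated across genes at r = 0.908 (0.5 in the simulation), with a covariance of 0.267 against 0.028 simulated, a difference of 0.239. Genes are not independent replicates, and 3 control arrays are too few to be split between the comparisons. The TsSP changes without and with inulin, which come from comparisons with no shared array, had a covariance of 0.232. This argues against the shared controls as the source of most of the excess, though a small part may come from them.

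TsSP was also compared between the inulin groups, which asks what TsSP adds when inulin is present and shares no array with the comparison of TsSP against LPS alone. Tnf was 6.93-fold lower with TsSP and inulin than with inulin (log2 SE 0.12, n = 3 per group, adjusted p = 4.94e-08), Il6 4.55-fold lower (log2 SE 0.11), Il27 36.2-fold lower (log2 SE 0.14), Il10 3.20-fold higher (log2 SE 0.13) and Il19 43.2-fold higher (log2 SE 0.18). limma called 3248 genes, 1689 higher and 1559 lower. Of the genes called for TsSP without inulin, 1420 were higher and 1102 lower here too (186 and 110 for independent lists), and 1, Aanat, which lay below background on the arrays, had opposite signs. Across genes the log2 changes without and with inulin correlated at r = 0.801. Among the lists, 29 of 33 cytokine genes and 38 of 40 interferon-stimulated genes fell (29 and 39 when adjusted over the list alone; medians -1.53 and -0.78, adjusted p = 7.80e-31 and 3.39e-29), and 18 of 21 cholesterol biosynthesis genes and 22 of 32 glycolysis and hypoxia genes rose (20 and 24 when adjusted over the list alone; medians 0.87 and 0.91, adjusted p = 7.90e-15 and 6.98e-17). The NRF2 list was called higher and the NF-kB, antigen presentation and p53 lists lower, at adjusted p = 2.34e-11, 5.53e-13, 2.57e-07 and 0.0126, the last with adjusted p = 0.249 with an estimated correlation.

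**Figure D3:**
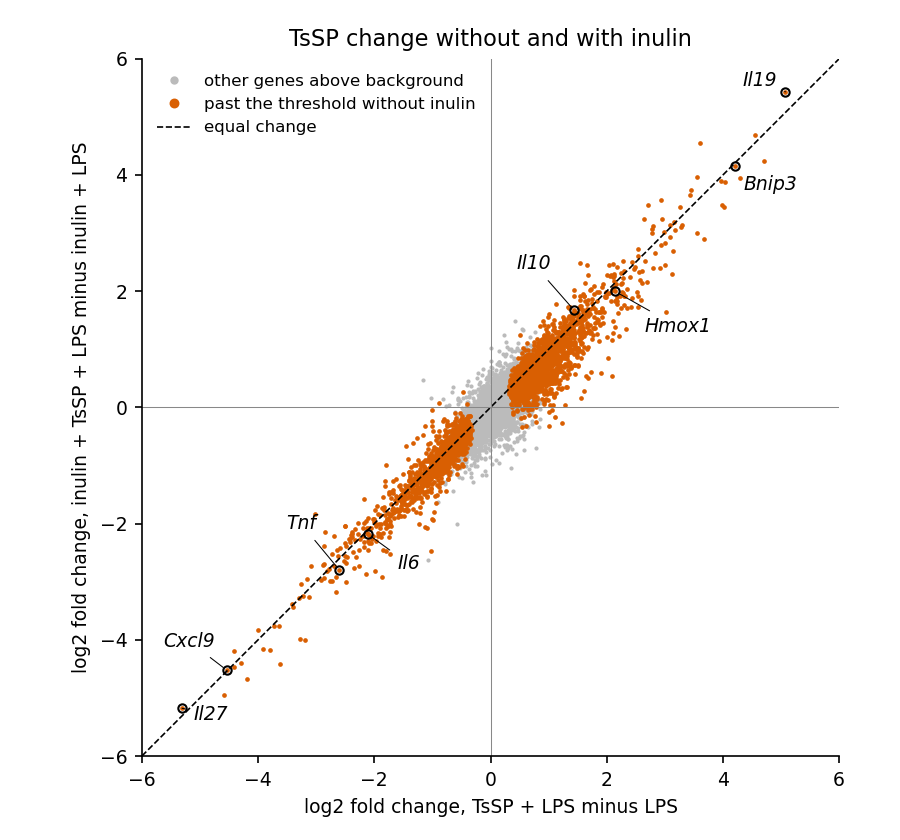
Log2 fold change with TsSP in the presence of LPS alone (horizontal axis) against the log2 fold change with TsSP in the presence of inulin and LPS (vertical axis), one dot for each of the 9022 genes above background, orange where the change without inulin passed the threshold, with a dashed line of equal change. The axes share no arrays, and named genes such as Il27, Cxcl9, Tnf, Il6, Il10, Hmox1, Bnip3 and Il19 lie near the line.

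What inulin adds when TsSP is present was tested between the TsSP groups. Tnf differed by -0.14 on the log2 scale (SE 0.12, n = 3 per group, adjusted p = 0.993), Il6 by -0.083 (SE 0.11) and Il10 by -0.030 (SE 0.13), and no gene passed. limma called 0 genes, with 971 at an unadjusted p under 0.05 where 975 would be expected with no effect, and a smallest adjusted p of 0.876. No list passed camera, the smallest adjusted p being 0.0921 for the LXR and lipid list, with a median log2 difference of -0.083. When adjusted over the list alone, 1 anti-inflammatory regulator, the cytokine signalling inhibitor gene Socs1, was lower, by -1.07 on the log2 scale, against an adjusted p of 0.876 over all genes. Without replicate 2 of the combined group the LXR and p53 lists passed, at adjusted p = 0.0218 and 0.0412. The 95% interval lay within 2-fold for 97.1% of the genes above background.

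Whether the combined change departed from the sum of the single changes on the log2 scale was tested as an interaction. It was -0.19 for Tnf (SE 0.16, adjusted p = 0.97), -0.082 for Il6 (SE 0.16), 0.24 for Il10 (SE 0.18) and -0.15 for Hmox1 (SE 0.14). limma called 0 genes, with 1089 at an unadjusted p under 0.05 and a smallest adjusted p of 0.646, and camera, its estimated-correlation form and fry called 0 of 26 lists. Among genes above background, Ube2t and the kelch protein gene Klhl2 had among the smallest p-values, at -1.5 (SE 0.25) and -1.08 (SE 0.20). The 95% interval of the interaction lay within 2-fold for 85.4% of the 9022 genes above background. A limma F test over the 4 groups called 3655 genes, for which the median size of the log2 change was 0.75 for TsSP, 0.11 for inulin and 0.16 for the interaction.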

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

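The test on the background probes of LPS replicate 1 was chosen only after that array had been seen to stand apart. Among the 2634 transcript clusters with no gene name here, 264 passed the limma threshold, adjusted over all 28846 probe sets, between TsSP with LPS and LPS alone, 165 higher and 99 lower, and 233 of them lay above background in a group. Among the 5222 intron control probe sets, 112 passed, 74 higher and 38 lower, and 31 of them lay above background. Among the 1324 exon control probe sets, 164 passed, 129 higher and 35 lower, with a median log2 change of 0.17, while 0 of 23 background probes and 0 of 71 spike and hybridization controls passed, with 0 and 3 at an unadjusted p under 0.05.

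LPS replicate 1 stood apart on the second principal component, with a score of 41.8 where the other arrays lay between -19.6 and 5.19. Its gene signals lay below the mean of the other LPS arrays at every level of brightness, with median log2 differences of -0.13, -0.17, -0.12 and -0.079 in 4 equal bins of genes from the dimmest to the brightest. Its background probes, which match no cell RNA, had a median of 4.99 against 5.2 in the lowest other array, so part of the difference may be array-wide. Its intron control median was 4.66, against 4.70 on each of the other LPS arrays. On it 8837 genes lay above background, against 8771 and 8835 on those arrays. Changes in particular genes were not separated from an array-wide shift and stay open. Without LPS replicate 1, the genes called for TsSP numbered 3090 and the share of higher calls was 55.7%, so the array moved the balance of rises and falls. Whether the difference arose in the culture, the RNA or the hybridization stays open, and no biological explanation was tested.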

How the results depend on the processing

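Leaving out each array in turn and the block for the replicate number were planned, and the alternatives named in the methods as added were chosen only after the data had been seen. The genes called numbered 2753 to 3452 for TsSP, 2629 to 3326 for the combination, 2523 to 3337 for TsSP added to inulin and 3187 to 3512 for any difference with 1 array left out, and 0 for both inulin contrasts and the interaction; the list calls numbered 25 to 30. The shared calls of TsSP and the combination were counted only without each LPS array in turn, and numbered 2414 to 2481. These counts stayed within 1.5 times the value with all arrays. With fry, 52 list calls were made against 27 with camera, since fry asks another question. At an adjusted p under 0.01, 1768 genes were shared by the TsSP and combined comparisons against 2851, by construction. No single-gene or list result changed direction where it was called in either fit. Of 260 single-gene results under 6160 alternatives, 5999 stayed the same, 109 lost and 30 gained a call, and 22 changed direction without a call in either fit. Of 156 list results under 2496, 2352 stayed the same, 10 lost and 30 gained a call, and 104 changed direction without a call in either fit. No pairing of the arrays by replicate number was seen: in 18 pairs of groups and numbers the deviations from the group means correlated at r = -0.0936 to 0.105, with 1 over 0.1. Arrays with different numbers were not correlated for reference, so a weak pairing stays open. With the replicate block the calls numbered 3203, 0, 3093, 0, 2941 and 0 in the order TsSP, inulin, combination, inulin added, TsSP added and interaction, with 3297 for any difference, 27 list calls and 2559 shared genes. For TsSP the block ended the calls of Pfkp, Myc, Atp6v1a and Maf, at adjusted p = 0.0588, 0.0779, 0.0530 and 0.0559. It added a call of Mcpt4 as lower, at adjusted p = 0.0366. The average of both inulin contrasts called 0 genes (limma, 1047 at an unadjusted p under 0.05, smallest adjusted p 0.528). The alternative of another pseudocount was not run, since the deposited values are already logarithms. Signal over background limits the folds of dim genes, and 9022 of 19505 genes lay above background on all arrays of a group.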

Other observations

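The tests on brightness and scaling, the GTPase list and the intervals of the cAMP list were chosen only after the results they bear on had been seen, as were the restriction of the inulin correlation to genes above background and its regroupings over all genes. The HIF, cAMP and SREBP1 lists were drawn up after the fixed lists had been tested but before they were tested as lists. Their members that are also in fixed lists had already been tested there.

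The immunity-related and guanylate-binding GTPases are interferon-inducible proteins that act against pathogens inside cells. With TsSP all 14 measured members fell, with a median log2 change of -1.60. The list was drawn up after Iigp1 and Tgtp2 had been seen among the largest falls, so its count is a description and no test of the group. The interferon-inducible Iigp1 fell 12.5-fold and Gm4951 9.77-fold (n = 3 per group), Tgtp2 fell 13.9-fold, and Gm4841 was at least 9.55-fold lower. Some members are near-identical, so the count does not stand for 14 separate measurements. With inulin the median of the same genes was 0.0019, and 0 of 14 passed.

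The fall of cytokine and interferon-stimulated genes with TsSP had a median log2 change of -0.92 over the 68 members above background. The lowest median of 10000 random gene lists of the same brightness was -0.21, which argues against a loss of bright signals in general on the TsSP arrays. Compression alike on all arrays could not be seen in this way. After quantile normalization the median was -0.93, so scaling between arrays did not account for the fall. The array medians, from 5.16 to 5.3, already left that normalization little room to move such a change. A cAMP-type response, which would lower cytokines and raise Il10, is a hypothesis that the cAMP-responsive genes did not bear out as a set. Of those above background 31.8% rose. Over all 24 measured, 7 rose, Il10 itself among them, and 10 fell. Their median of -0.040 met the bound set against that hypothesis beforehand. So did -0.33 over members above background, -0.36 in the combined comparison and -0.24 for TsSP added to inulin. For TsSP added to inulin, 22.7% of the members above background rose, which also met a bound set against it beforehand. Members went both ways, however, so a response in part of them stays open. Resampled intervals, added later, all reach above 0 (-0.85 to 0.62 for the first median, and -0.84 to 0.45 in another run of the resampling). They came from resampling the listed genes and not the arrays. They therefore do not measure the spread between samples and cannot set those bounds aside. Of the 9 members in no fixed list 4 rose and 4 fell, with a median of 0.41. TsSP was absent or present by design, and whether a component of the preparation, less cell survival or a changed response to LPS lowered these genes was not tested.

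The metabolic lists were also read through their known regulators, and these readings were tested as hypotheses. A HIF-type response may accompany the rise of glycolysis and hypoxia genes: 84.2% of HIF targets outside glycolysis that lay above background rose, 16 of 19, with 0 falling (camera p = 6.08e-05 with an estimated correlation). Most of those targets are also in a list fixed beforehand and already tested, so the count and the camera p largely restate that rise. Of the 8 that are not, 7 rose, with a median log2 change of 1.24, and these 8 were not tested as a set. A general SREBP response may accompany the rise of cholesterol synthesis genes, since 81.8% of the SREBP1 lipogenic targets above background rose, 9 of 11 (camera p = 0.0265 with an estimated correlation). Of the 8 SREBP1 targets outside the fixed lists, 6 rose. The SREBP1 list did not pass with an estimated correlation in the combined comparison (p = 0.0754, 7 of 11 rose) or for TsSP added to inulin (p = 0.0628, 6 of 11 rose). Neither test measures HIF or SREBP protein, and other regulators of the same genes stay open.

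The absence of calls for inulin was weighed against low power and against a small shared effect. In a simulation of this contrast with 200 changed genes, all above background, 88.0% of 2-fold and 34.0% of 1.5-fold changes were recovered. The first met the bound set beforehand against too few arrays. That bound was too lenient, since many changed genes ease the adjusted threshold. Low power for a few changed genes and for dim genes stays open. Among genes above background, 4 had an estimated inulin change over 2-fold and 0 were called, against 1042 of 1049 for TsSP (limma; over all 19505 genes, 1143 had an unadjusted p under 0.05 for inulin, where 975 would be expected with no effect). A small inulin effect shared by both arms would make the inulin changes without and with TsSP correlate: across genes above background r was 0.030, and 96 of 400 regroupings of arrays gave as high a value. Across all genes r was -0.014, which met the bound set beforehand against a shared effect, but 284 of 400 regroupings over all genes gave as high a value (SD 0.022, and 0.036 above background), so such an effect could neither be seen nor excluded.

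Other groupings of the same arrays were counted with limma. For any difference between the 4 groups, 1 of 100 drawn splits, the real one, gave as many genes, with 3655 against a highest other of 0. Arrays with and without TsSP therefore differed beyond the spread between single arrays. This count does not show a difference among all 4 groups, since both inulin contrasts and the interaction called 0 genes. The labels do not say that the arrays of a group came from separate cultures. Regrouping arrays therefore cannot exclude a chance difference between cultures. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05: the real values and the highest others were 3525 and 0 for TsSP, 3433 and 0 for the combination, 3248 and 0 for TsSP added to inulin, 0 and 2 for inulin, and 0 and 0 for inulin added to TsSP. The splits as high as the real one numbered 1, 1, 1, 10 and 10 in that order. For the interaction, 100 of 100 splits drawn within the arms with and without TsSP reached the real value of 0, with a highest other of 1. Any split reaches a real value of 0, so the counts for the interaction and both inulin contrasts say nothing about chance.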
